A study of Rattus norvegicus with 17 samples.

How the data were processed

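Gene expression was measured in single neurons of the bilateral lumbar L4 to L5 dorsal root ganglia of male Sprague Dawley rats. Neurons were picked one at a time by mouth pipette and amplified with a modified Smart-seq2 protocol whose oligo(dT) primer carries an 8 nt cell barcode and an 8 nt UMI, so the libraries count the 3' ends of polyadenylated RNA. They were sequenced on an Illumina instrument. The labels list 17 samples, each a batch of pooled cells, with 1080 labelled cells in 1 group. The protocols describe plating for 15 minutes and for 72 hours, with at least 5 rats per time point, and neither the time point nor the animals of a batch are given in the sources used here.

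Per the labels, the authors processed the reads with UMI-tools, STAR, featureCounts, Subread and SAMtools against Rnor_6.0, and the labels list these names without versions or settings. The deposited values are UMI counts per gene and cell in 32883 gene rows, and they were checked to be whole numbers. The strand setting of the counting is not given in the sources used here. The counts of batch 21 were identical to those of batch 20 and carried its cell names, so 16 batches with 1040 cells were used and the 40 labelled cells of batch 21 were not analysed here. No other cells had identical counts.

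Cells with at least 2000 detected genes were kept (967 of 1040, with 4307 to 1514406 UMIs). Batch totals ran from 3812280 to 26065847 UMIs. Counts were scaled to 100000 per cell and log-transformed, and cells were clustered on a panel of cell type markers (90 of 109 listed genes, after leaving out 10 that were not in the counts and those with UMIs in fewer than 10 cells), with 15 principal components, 15 neighbours and Leiden clustering at a resolution of 1. A cluster took a class's name when at least 3 of the class's markers were raised by at least 0.5 on the log2 scale (10 CPM added) and it spread over at least 8 batches. Clusters led by glial, haemoglobin or no class's markers entered no comparison. The names end in "-like" because the labels give no cell types. NF stands for neurofilament, PEP for peptidergic, NP for non-peptidergic, PRUR for pruriceptor, CLTMR for C-low-threshold mechanoreceptor and TRPM8 for neurons with that channel. Cells were picked singly and no doublet caller was run.

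UMIs were summed per batch and class where a batch held at least 3 cells of the class, which gave 66 sums (16 NP-like, 15 PEP-like, 11 CLTMR-like, 9 PRUR-like, 8 TRPM8-like and 7 NF-like). These were fitted together with edgeR 4.0.16 (filterByExpr with a minimum count of 10, TMM factors, quasi-likelihood F-test with class and batch as terms), with Benjamini-Hochberg adjustment over 12082 genes and a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the square root of F. The 64 panel genes among those tested were left out of counts and named genes, because they had defined the classes. CPM of class sums use TMM-scaled totals, and CPM of clusters and of detection are plain. The comparisons share libraries, so their gene counts are not independent, and no overlap between comparisons was tested. Each of the other 3 classes was compared with the mean of the remaining 5. Their counts of batches higher or lower set the class against the mean of whichever other classes the batch held. Batches holding both classes numbered 7 for NF-like against NP-like and against PEP-like and 15 for PEP-like against NP-like.

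The 15 gene lists, the marker panel, the comparisons and most alternatives were written before the data were examined. The lists cover regeneration-associated genes, growth cone and cytoskeleton, growth brakes, the mTOR and PI3K pathway, growth factor receptors, axon guidance receptors, integrins and matrix receptors, axonal transport, sodium, potassium and HCN channels, TRP, Piezo, ASIC and purinergic channels, oxidative phosphorylation, cholesterol synthesis, immediate-early and stress genes, neuropeptides and granins, and ribosomal proteins. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 15 lists of a comparison. Named genes were the 6 with the largest log2 fold change in each direction among called genes with at least 50 CPM in the higher class, the same direction in at least 80% of batches and a gene symbol, and up to 2 members per list and direction, of which the text gives a part; some results are not reported here. Atf3, Sprr1a, Gap43, Sox11, Jun and Gal are given in every comparison, and Npy, also fixed, was too low to be tested. Lists of other cell types (glia, fibroblasts, vessels, immune cells and blood) were compared the same way. Their tested members are panel genes and, unlike elsewhere, were kept in these counts, which are therefore no independent test. Depth per cell was compared by sign-flip tests over batches, exact with 7 batches and with 100000 draws with 15. The Sst and Nppb relation used 100000 permutations and 2000 bootstraps.

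Choices made after the data were seen were the filter of 2000 genes, the thresholds for naming a cluster, the use of the rule on the largest changes for the other 3 classes, the leaving out of further non-coding RNA names from it, and edgeR's default deviance, kept after the counts with the bias-adjusted deviance were seen. The alternatives added then are named as such in the closing section. Alternatives were RLE factors, DESeq2 1.42.0, no low-count filter, at least 5 or 8 cells per sum, no cell filter or 3000 genes, clusters from 2000 highly variable genes, the panel centred per batch, Leiden resolutions of 0.5 and 2, cells thinned to 30000 UMIs, cells high in glial markers left out, batches 28-1 and 28-3 as 1 batch, and each batch left out in turn.

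The fit was tested on simulated data with the depths and mean gene levels of the same sums. Of 100 genes changed 2-fold it recovered 43% to 65% over the 6 comparisons, and of 100 changed 4-fold 79% to 95%, with 3.92% to 6.57% false calls. Camera gave 6.95e-43 for a simulated list of 30 members changed 1.5-fold and 0.567 for an unchanged one. The simulated genes were drawn independently of each other and without batch differences beyond depth. So neither the false calls nor the set test was tried on genes that vary together. Estimated correlations of the real lists reached 0.474. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 were used.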

Results

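The series asks which mechanisms set the different axonal growth capacity of sensory neuron subtypes. It profiled single neurons of the lumbar dorsal root ganglia of male Sprague Dawley rats. Each was picked by mouth pipette and amplified with a modified Smart-seq2 protocol that counts the 3' ends of polyadenylated RNA with unique molecular identifiers (UMIs). The 17 samples are batches of pooled cells and form 1 group in the labels, so neuron classes were compared within batches and no treatment was compared. The protocols describe both a plating of 15 minutes and one of 72 hours, and nothing in the labels says which batch had which. The counts given for batch 21 were identical to those of batch 20 and carried its cell names, so they were used once. The 40 labelled cells of batch 21 were not analysed here. The other 16 batches held 1040 cells and between 3812280 UMIs (batch 28-1) and 26065847 UMIs (batch 20). Of these cells, 967 had at least 2000 detected genes and were kept, with a median of 139374 UMIs and 8302 genes per cell. The batches are not stated to be separate animals, so p-values measure no spread between animals. Those of genes measure the spread that remains between sums once class and batch are fitted, estimated over all classes together. That spread may be technical, and a class with a wider spread of its own is not judged by it alone.

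The kept cells fell into 6 neuron classes, called after markers fixed before the data were examined, and together they took in 730 of the kept cells (75.5%). NF-like cells carried Pvalb, a calcium-binding protein of proprioceptors, at a mean of 174 CPM over their batch sums and Spp1 at 281 CPM, against 2.13 and 23.8 CPM in NP-like cells. PRUR-like cells, named after itch receptors, carried the peptides Sst at 1199 CPM and Nppb at 721 CPM. PEP-like cells had the highest mean of the 6 classes for Calca, the precursor of the peptide CGRP, at 1926 CPM, and for the receptor tyrosine kinase Kit at 211 CPM. TRPM8-like cells carried the cold-activated channel Trpm8 at 125 CPM. NP-like cells carried the ATP-gated channel P2rx3 at 448 CPM. In contrast, Mrgprd, a receptor typical of non-peptidergic nociceptors, was at 0.170 CPM there and had a UMI in 5 of 302 cells (1.66%, exact 95% interval 0.540 to 3.82%). The interval counts cells as independent and measures no spread between batches. CLTMR-like cells carried Tafa4 at 42.0 CPM and Zfp521 at 39.8 CPM, but Zfp521 was also at 36.1 CPM in TRPM8-like cells. In contrast, Th, a usual marker of C-low-threshold mechanoreceptors, was at 2.48 CPM in CLTMR-like and at 31.3 CPM in NP-like cells. Of the same marker list, Slc17a8 was at 0 CPM in CLTMR-like cells. P2ry1 was at 7.09 CPM there and at 6.54 CPM in NF-like cells. The CLTMR-like class and the largest NP-like cluster rest on 3 raised markers each, with none among their 10 leading genes, and those 2 names are the least certain.

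The NP-like class took a mean share of 33.9% ± 14.7 of a batch's kept cells (SD, n = 16 batches, range 16.9 to 71.9%) and the PEP-like class 20.5% ± 8.95. The CLTMR-like class took 6.27% ± 4.06, the PRUR-like class 6.08% ± 3.41, the NF-like class 5.13% ± 4.31 and the TRPM8-like class 3.94% ± 2.66. Cells were picked under a microscope, so these shares describe the picked cells and not the ganglion. With clusters from highly variable genes the shares were 10.06% (NP-like), 13.54% (PEP-like), 5.62% (PRUR-like), 8.04% (NF-like) and 4.08% (TRPM8-like), no cluster met the rule for the CLTMR-like name, and 557 cells fell in no class. A cluster of 64 cells led by Atp2b2 and Nmu, as the CLTMR-like class is here, and one of 92 cells led by Th both came nearest to that name there. The remaining 237 cells belonged to clusters led by glial genes (56 cells), by haemoglobin genes (47 cells) or by no class's markers (134 cells, with a median of 16470 UMIs). They entered no comparison. Summing UMIs per batch and class, where a batch held at least 3 cells of it, gave 66 sums of 155695 to 11248642 UMIs and 12082 tested genes.

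NF-like and NP-like neurons, the large myelinated and the small non-peptidergic types of the marker panel, differed strongly in a subunit and a regulator of the sodium pump. Atp1b1, a beta subunit of the pump, was at 451 ± 165 CPM in NF-like sums (SD, n = 7) and 25.0 ± 17.9 CPM in NP-like sums (n = 16). The log2 fold change was 4.46 ± 0.30 (SE, adjusted p = 3.6e-17, higher in 7 of 7 batches). The pump regulator Fxyd7 was higher by 4.88 ± 0.40 (adjusted p = 5.12e-14, 365 against 12.8 CPM), also in 7 of 7 batches. Lower in NF-like neurons were the synaptic vesicle protein Synpr (-3.54 ± 0.29, adjusted p = 6.91e-14) and the RNA-binding protein Celf6 (-3.05 ± 0.30, adjusted p = 1.38e-11), each in 7 of 7 batches. In all, 837 genes were higher and 1470 lower in NF-like neurons at an adjusted p under 0.05. That count of 2307 was 729 with each cell thinned to 30000 UMIs, 1217 with NP-like cluster 6 alone, 1504 without batch 26, 3485 with limma voom and 4179 with a bias-adjusted deviance.

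Also higher was Pla2g7, a phospholipase that inactivates platelet-activating factor, at 5.57 ± 0.69 (adjusted p = 2.05e-08). So were Faim2, an inhibitor of Fas signalling, at 4.70 ± 0.50 (adjusted p = 2.25e-10, 6 of 7 batches) and Rprm at 4.61 ± 0.43 (adjusted p = 3.57e-12). Other lower genes were Stfa2l1 (-3.76 ± 0.69, adjusted p = 5.03e-05) and the extracellular matrix gene Aebp1 (-3.51 ± 0.59, adjusted p = 1.1e-05). They also included Ctla2a (-3.43 ± 0.49, adjusted p = 5e-07) and Abi3bp (-2.86 ± 0.65, adjusted p = 0.000845, lower in 6 of 7 batches). Stfa2l1 and Ctla2a belong to families of near-identical copies, so their counts are uncertain. Guidance receptors went both ways, with 5 of 28 members higher and 4 lower (adjusted over the list alone, 5 and 4). The semaphorin co-receptors Nrp2 (4.07 ± 0.50, adjusted p = 1.81e-08) and Nrp1 (2.68 ± 0.57, adjusted p = 0.000388) were higher. The adhesion molecule Ncam1 was lower (-1.03 ± 0.20, adjusted p = 8.9e-05). It was at 1.66 with clusters from highly variable genes, whose NF-like class shared 25 of its 81 cells with the one used here. Among growth factor receptors 4 of 20 were higher, among them the neurotrophin receptor Ngfr (1.35 ± 0.23, adjusted p = 1.17e-05). The 1 lower member was the GDNF-family receptor Ret (-0.98 ± 0.21, adjusted p = 0.000415). Sodium, potassium and HCN channels were split 8 higher and 7 lower of 37 (adjusted over the list alone, 10 and 8). They ran from Scn1a (5.17 ± 0.70, adjusted p = 1.53e-07) to the potassium channel Kcnk18 (-5.43 ± 0.92, adjusted p = 2.09e-05, 0.512 against 12.0 CPM).

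Members of the regeneration-associated list, fixed before the data were examined, were more often lower than higher in NF-like against NP-like neurons. Of 38 members 2 were higher and 16 lower (adjusted over the list alone, 2 and 17). The camera set test gave an adjusted p of 3.25e-05, with adjusted p = 0.447 with an estimated correlation. Plaur, the urokinase receptor, was lower by -1.74 ± 0.18 (adjusted p = 2.3e-10) and the endopeptidase Ecel1 by -1.64 ± 0.28 (adjusted p = 1.33e-05). In contrast, Csf1 (2.26 ± 0.58, adjusted p = 0.00319) and the activin antagonist Fst (3.10 ± 0.96, adjusted p = 0.016) were higher. Growth cone and cytoskeleton genes had 2 of 41 members higher and 13 lower (adjusted over the list alone, 2 and 15; set test adjusted p = 0.00177, adjusted p = 0.447 with an estimated correlation). Lower members included the collapsin response mediators Dpysl3 (-0.98 ± 0.17, adjusted p = 1.92e-05) and Crmp1 (-0.79 ± 0.13, adjusted p = 1.08e-05). Axonal transport genes had 2 of 40 higher and 15 lower (adjusted over the list alone, 2 and 16; set test adjusted p = 0.0135, adjusted p = 0.447 with an estimated correlation). Lower members included the kinesins Kif1a (-0.86 ± 0.14, adjusted p = 7.6e-06) and Kif3a (-0.58 ± 0.11, adjusted p = 0.000125). Ribosomal protein genes, many of which have near-identical copies, had 0 of 65 higher and 22 lower (adjusted over the list alone, 0 and 28; set test adjusted p = 8.64e-08, adjusted p = 0.447 with an estimated correlation). Of the injury and growth genes named in advance, Jun was lower by -0.60 ± 0.15 (adjusted p = 0.00312, lower in 5 of 7 batches, but 0.15 at a Leiden resolution of 2). The fixed genes Atf3 (-0.11 ± 0.16, adjusted p = 0.701), Sprr1a (-0.02 ± 0.22, adjusted p = 0.971), Gap43 (-0.34 ± 0.18, adjusted p = 0.185), Sox11 (-0.21 ± 0.27, adjusted p = 0.666) and Gal (-0.31 ± 0.30, adjusted p = 0.539) did not pass. Of the 7 NF-like sums, those of batches 28-3 and 32 stood apart. They held 3 cells each and the fewest UMIs, 184310 and 334383. The sum of batch 26, also of 3 cells, had 2566549 UMIs and lay with the rest. Whether depth bears on these levels was not tested. In batches 28-3 and 32 Gal was at 4060 and 2599 CPM, against 424 to 659 CPM in the other 5 NF-like sums. Gap43 was at 2689 and 2158 against 622 to 1106 CPM, and Sprr1a at 1051 and 802 against 274 to 385 CPM. Atf3 was at 997 and 726 against 403 to 478 CPM and Sox11 at 66.5 and 135 against 7.19 to 32.6 CPM. In the other 5 batches these 5 genes were lower in the NF-like than in the NP-like sum. With at least 5 cells per sum, which leaves out both sums and that of batch 26, Gap43 NF-like against NP-like was at -0.80 (adjusted p = 1.78e-05), Gal NF-like against NP-like at -1.19 (adjusted p = 7.59e-05) and Sprr1a NF-like against NP-like at -0.33 (adjusted p = 0.185). Sox11 NF-like against NP-like was then at -0.83 (adjusted p = 0.039) and Atf3 NF-like against NP-like at -0.32 (adjusted p = 0.12). With RLE factors Atf3 was at 0.07 and Sprr1a at 0.16. The median mitochondrial share of UMIs was 2.21% in NF-like and 1.48% in NP-like cells, and whether it bears on these lists was not tested. Glial markers had 2 of 9 tested members higher and 0 lower in NF-like neurons (median 1.03), at a summed 1943 against 1100 CPM. These belong to the panel that formed the classes, so their counts are no independent test. One of the list, S100b, was among the 10 leading genes of the NF-like cluster, so the summed level is no clean measure of glial RNA. Of 5 core glial genes, chosen after the data were seen, 3 were tested and 0 passed (median 1.12). Their summed level was 69.4 ± 94.9 CPM in NF-like and 16.8 ± 6.15 CPM in NP-like sums.

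The set test passed for no other list, and where no second count is given here and below, adjustment over the list alone left the counts as they are. Growth brakes had 0 of 27 members higher and 4 lower (median -0.14, mean 0.02, and a median of 0.04 with RLE factors), the mTOR and PI3K pathway 1 of 27 higher and 4 lower. Integrins and matrix receptors had 3 of 24 higher and 7 lower. Oxidative phosphorylation had 1 of 37 higher and 8 lower (adjusted over the list alone, 2 and 8; median -0.08, and 0.09 with RLE factors). Cholesterol synthesis had 0 of 25 higher and 7 lower, and TRP, Piezo, ASIC and purinergic channels 4 of 19 higher and 1 lower. Immediate-early and stress genes had 1 of 16 higher and 0 lower. Neuropeptides and granins had 4 of 17 higher and 5 lower (adjusted over the list alone, 5 and 5; median -0.05, mean 0.24), led by Nmb (3.77 ± 0.64, adjusted p = 1.52e-05). RLE scaling factors raised the median over all genes by 0.17 and turned the split of calls to 1248 higher and 710 lower. With them the counts were 3 and 8 in the regeneration list, 2 and 6 in the growth cone list, 3 and 3 in the transport list, 0 and 9 in the ribosomal list and 3 and 0 in the growth brakes. They were 2 and 1 in oxidative phosphorylation, 1 and 2 in cholesterol synthesis, 1 and 2 in the mTOR and PI3K pathway, 3 and 5 in the integrins and 5 and 3 in the neuropeptides. They were 10 and 6 in the sodium, potassium and HCN channels, 4 and 0 in the TRP, Piezo, ASIC and purinergic channels and 2 and 0 in the immediate-early genes, and as before in the guidance and growth factor receptors. Jun was then at -0.42 (adjusted p = 0.054). Relative to the median of all genes, the regeneration list's median was -0.40 with TMM and -0.41 with RLE factors. A change of factors moves all genes nearly alike, so these values stay close by construction.

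PEP-like and NP-like neurons, the peptidergic and non-peptidergic nociceptor types of the panel, differed in the level of Clmp and Fcgrt. Clmp, an adhesion molecule of cell junctions, was at 141 ± 46.9 CPM in PEP-like sums (n = 15) and 3.80 ± 2.38 CPM in NP-like sums (n = 16). The log2 fold change was 5.16 ± 0.30 (adjusted p = 1.75e-20). Fcgrt, the neonatal Fc receptor, was higher by 4.65 ± 0.24 (adjusted p = 4.85e-23) and the guanine deaminase Gda by 4.51 ± 0.53 (adjusted p = 1.2e-09), each in 15 of 15 batches. The same held for Ramp3, a partner of the calcitonin receptor-like receptor, at 4.03 ± 0.38 (adjusted p = 1.94e-12). Lower in PEP-like neurons were the nicotinic receptor subunit Chrna3 (-4.38 ± 0.35, adjusted p = 6.53e-15) and the stress hormone precursor Crh (-4.29 ± 0.50, adjusted p = 6.7e-10), each in 15 of 15 batches. In all, 917 genes were higher and 1304 lower in PEP-like neurons.

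Further large differences were Ifitm2 (3.50 ± 0.33, adjusted p = 1.94e-12) and the retinol carrier Rbp4 (3.48 ± 0.43, adjusted p = 4.55e-09, 13 of 15 batches) on the PEP-like side. On the NP-like side they were Ctla2a (-4.58 ± 0.34, adjusted p = 2.51e-16) and Gzmbl3 (-4.12 ± 0.48, adjusted p = 1.07e-09). They also included Stfa2l1 (-3.85 ± 0.48, adjusted p = 6.25e-09) and the desmosomal gene Perp (-3.65 ± 0.26, adjusted p = 2.91e-17). Gzmbl3 and Ifitm2 also have close copies and are uncertain. Neuropeptide and granin genes had 8 of 17 members higher and 2 lower (adjusted over the list alone, 8 and 3; set test adjusted p = 0.00295, adjusted p = 0.0556 with an estimated correlation). The list's median was at 0.36 and its mean at -0.04. Higher were Cck (1.99 ± 0.20, adjusted p = 7.58e-12) and the amidating enzyme Pam (0.97 ± 0.12, adjusted p = 4.27e-09), and lower were Crh and Nts (-3.69 ± 0.63, adjusted p = 7.62e-06). The acid-sensing channels Asic3 (2.63 ± 0.25, adjusted p = 1.38e-12) and Asic1 (1.88 ± 0.21, adjusted p = 2.31e-10) were higher. The mechanically gated channel Piezo2 was lower (-1.74 ± 0.20, adjusted p = 6.03e-10), within a list of 19 that had 3 higher and 3 lower (adjusted over the list alone, 3 and 4; median -0.03, mean 0.02). Sodium, potassium and HCN channels had 8 of 37 higher and 10 lower. They ran from Kcnk3 (3.76 ± 0.55, adjusted p = 2.67e-07) to Kcnk18 (-5.51 ± 0.58, adjusted p = 1.77e-10).

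Cholesterol synthesis genes were higher in PEP-like neurons in 12 of 25 cases and lower in 1 (adjusted over the list alone, 15 and 1; set test adjusted p = 6.83e-06, adjusted p = 0.18 with an estimated correlation). Fdft1, squalene synthase, was at 0.59 ± 0.10 (adjusted p = 6.22e-06) and the sterol oxidase Msmo1 at 0.60 ± 0.11 (adjusted p = 4.36e-05). The regeneration list had 9 of 38 members higher and 5 lower (adjusted over the list alone, 10 and 5; set test adjusted p = 0.00728, adjusted p = 0.41 with an estimated correlation). Its members with the smallest p were the adhesion molecule Chl1 (2.47 ± 0.24, adjusted p = 3.37e-12) and the transcription factor Myc (1.21 ± 0.16, adjusted p = 1.82e-08) on the higher side. On the lower side they were the laminin-binding integrin Itga7 (-1.47 ± 0.21, adjusted p = 1.49e-07) and Cebpd (-1.42 ± 0.27, adjusted p = 4.23e-05). Oxidative phosphorylation had 6 of 37 higher and 0 lower (adjusted over the list alone, 6 and 0; set test adjusted p = 0.000147, adjusted p = 0.41 with an estimated correlation). With RLE factors 2 were higher. Ribosomal protein genes had 15 of 65 higher and 1 lower (adjusted over the list alone, 20 and 1; set test adjusted p = 1.3e-08, adjusted p = 0.41 with an estimated correlation). Of the genes named in advance, Atf3, a transcription factor induced by axon injury, was higher by 0.42 ± 0.12 (adjusted p = 0.00695, 813 ± 126 against 624 ± 119 CPM, 13 of 15 batches). The peptide Gal was higher by 0.68 ± 0.21 (adjusted p = 0.0143, 13 of 15 batches). Sprr1a (0.31 ± 0.16, adjusted p = 0.176), Gap43 (0.30 ± 0.13, adjusted p = 0.0949), Jun (0.16 ± 0.11, adjusted p = 0.359) and Sox11 (-0.06 ± 0.19, adjusted p = 0.883) did not pass.

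For the other lists the set test did not pass. Guidance receptors had 7 of 28 members higher and 7 lower. They ran from Dcc (2.80 ± 0.62, adjusted p = 0.000564) to Robo1 (-4.30 ± 0.67, adjusted p = 1.24e-06; median -0.13, with the set test pointing up). Epha5 was at 1.72 ± 0.29 (adjusted p = 4.15e-06). Integrins and matrix receptors had 3 of 24 higher and 3 lower (median 0.01, and -0.02 with RLE factors). The tetraspanin Cd9 was at 3.26 ± 0.31 (adjusted p = 1.94e-12) and the kindlin Fermt2 at -0.95 ± 0.11 (adjusted p = 7.53e-10). Growth brakes had 3 of 27 higher and 5 lower (adjusted over the list alone, 3 and 7). Growth factor receptors had 3 of 20 higher and 4 lower (adjusted over the list alone, 4 and 4; median 0.17, mean -0.02). The mTOR and PI3K pathway had 2 of 27 higher and 0 lower (median -0.10, with the set test pointing up). Growth cone genes had 3 of 41 higher and 0 lower (adjusted over the list alone, 1 and 0). Transport genes had 4 of 40 higher and 0 lower (adjusted over the list alone, 2 and 0), and immediate-early genes 4 of 16 higher and 0 lower. With RLE factors the counts were 8 and 5 (regeneration), 11 and 1 (cholesterol), 11 and 1 (ribosome), 3 and 6 (growth brakes), 1 and 1 (growth cone), 2 and 1 (transport), 2 and 1 (mTOR), 3 and 4 (integrins) and 7 and 10 (sodium, potassium and HCN channels). The count of calls was 1320 when each cell was thinned to 30000 UMIs, a fit that tested 6797 genes. It was 1111 with NP-like cluster 6 alone, 4097 with the bias-adjusted deviance and 4565 with limma voom.

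Between NF-like and PEP-like neurons, 1284 genes were higher and 1757 lower in the NF-like class. Pla2g7 was at 91.7 ± 80.9 CPM in NF-like sums (n = 7) and 1.35 ± 1.39 CPM in PEP-like sums (n = 15). The log2 fold change was 5.92 ± 0.74 (adjusted p = 1.31e-08, higher in 6 of 7 batches). The homeobox transcription factor Shox2 was higher by 5.56 ± 0.80 (adjusted p = 4.21e-07, 6 of 7 batches). The actin regulator Baiap2l1 was higher by 4.77 ± 0.46 (adjusted p = 2.33e-11, 7 of 7 batches). Lower in NF-like neurons were the matricellular protein Ccn3 (-4.70 ± 0.77, adjusted p = 4.93e-06) and the hyaluronan-binding protein Tnfaip6 (-3.93 ± 0.68, adjusted p = 1.17e-05, 6 of 7 batches). Lower too was Il2rg, the shared gamma chain of interleukin receptors (-2.95 ± 0.36, adjusted p = 5.78e-09). Dhrs2 (5.41 ± 0.81, adjusted p = 9.18e-07) and Ccdc172 (4.99 ± 0.61, adjusted p = 7.25e-09) were also higher. Further genes were lower, namely Apoh (-3.43 ± 0.41, adjusted p = 4.18e-09), Celf6 (-3.06 ± 0.30, adjusted p = 2.39e-11) and Synpr (-2.73 ± 0.29, adjusted p = 2.48e-10).

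The regeneration list was lower in NF-like than in PEP-like neurons in 22 of 38 members and higher in 2 (adjusted over the list alone, 23 and 3; set test adjusted p = 6.01e-09, adjusted p = 0.121 with an estimated correlation). The calcium channel subunit Cacna2d1 was at -1.47 ± 0.18 (adjusted p = 1.55e-08) and Plaur at -1.64 ± 0.18 (adjusted p = 1.08e-09), each lower in 7 of 7 batches. Itga7 was higher (1.12 ± 0.29, adjusted p = 0.00234, but -0.17 with at least 8 cells per sum). Of the genes named in advance, Jun (-0.76 ± 0.15, adjusted p = 0.000125, lower in 7 of 7 batches, but 0.02 at a Leiden resolution of 2) and the growth cone protein Gap43 (-0.64 ± 0.18, adjusted p = 0.00512, 5 of 7) were lower. So were Atf3 (-0.53 ± 0.16, adjusted p = 0.0104, 6 of 7) and Gal (-0.99 ± 0.30, adjusted p = 0.0109, 6 of 7). Sprr1a (-0.33 ± 0.22, adjusted p = 0.279) and Sox11 (-0.15 ± 0.27, adjusted p = 0.75) did not pass. Cholesterol synthesis genes were lower in 15 of 25 cases and higher in 1 (adjusted over the list alone, 19 and 1; set test adjusted p = 4.02e-07, adjusted p = 0.121 with an estimated correlation). Fdft1 was at -1.39 ± 0.15 (adjusted p = 1.78e-10) and Cyp51 at -1.20 ± 0.17 (adjusted p = 5.1e-07). Transport genes had 17 of 40 lower and 2 higher (adjusted over the list alone, 20 and 2; set test adjusted p = 8.54e-05, adjusted p = 0.139 with an estimated correlation). Kif1a was at -1.02 ± 0.14 (adjusted p = 1.63e-07) and the dynein regulator Ndel1 at -0.53 ± 0.10 (adjusted p = 1.91e-05). Growth cone genes had 16 of 41 lower and 2 higher (adjusted over the list alone, 19 and 2; set test adjusted p = 3.77e-05, adjusted p = 0.27 with an estimated correlation). The microtubule-binding kinase Dclk1 was at -0.95 ± 0.14 (adjusted p = 7.15e-07). Glial markers had 2 of 9 tested members higher and 0 lower in NF-like than in PEP-like neurons (median 1.10), at a summed 1943 against 1051 CPM. They too belong to the panel that formed the classes, and the list includes S100b. Of the 5 core glial genes 3 were tested, with 1 higher and 0 lower (median 1.47).

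Ribosomal protein genes had 51 of 65 members lower and 0 higher (adjusted over the list alone, 52 and 0; set test adjusted p = 1.18e-19, adjusted p = 0.139 with an estimated correlation). Oxidative phosphorylation had 14 of 37 lower and 1 higher (adjusted over the list alone, 17 and 1; set test adjusted p = 8.54e-05, adjusted p = 0.324 with an estimated correlation). Sodium, potassium and HCN channels moved the other way, with 10 of 37 higher and 5 lower (adjusted over the list alone, 10 and 5; set test adjusted p = 0.00977, adjusted p = 0.169 with an estimated correlation). Scn4b, an accessory sodium channel subunit, was at 2.65 ± 0.29 (adjusted p = 3.36e-10). The potassium channel Kcnk1 was at 3.44 ± 0.41 (adjusted p = 4.18e-09) and Kcnk2 at -4.20 ± 0.62 (adjusted p = 7.16e-07). Among TRP, Piezo, ASIC and purinergic channels (adjusted over the list alone, 7 and 6) 7 of 19 were higher, with Piezo2 at 1.61 ± 0.26 (adjusted p = 3.97e-06). Lower were 4, with Asic3 at -1.45 ± 0.33 (adjusted p = 0.000593). Guidance receptors had 8 of 28 higher and 4 lower. They ran from Robo1 (5.15 ± 0.83, adjusted p = 3.08e-06) to Dcc (-3.99 ± 1.12, adjusted p = 0.00616), with Ncam1 at -1.81 ± 0.20 (adjusted p = 1.04e-09). Neuropeptides and granins had 5 of 17 higher and 8 lower (adjusted over the list alone, 5 and 9; median -0.34, mean 0.28). Integrins and matrix receptors had 3 of 24 higher and 10 lower (adjusted over the list alone, 4 and 10) and growth brakes 5 of 27 higher and 4 lower. The mTOR and PI3K pathway had 3 of 27 higher and 5 lower (median -0.19, and 0.02 with RLE factors). Growth factor receptors had 3 of 20 higher and 2 lower (adjusted over the list alone, 4 and 2) and immediate-early genes 0 of 16 higher and 1 lower. The set test passed for none of these lists. RLE factors raised the median over all genes by 0.21 and turned the split of calls to 2047 higher and 894 lower. The lists then had 3 and 16 (regeneration), 1 and 9 (cholesterol), 3 and 8 (transport), 3 and 9 (growth cone), 0 and 25 (ribosome) and 2 and 4 (oxidative phosphorylation). Growth brakes had 9 higher and 0 lower (median 0.33, and 0.12 with TMM). The others had 3 and 2 (mTOR), 6 and 2 (growth factor receptors), 4 and 7 (integrins), 6 and 5 (neuropeptides), 13 and 4 (sodium, potassium and HCN channels), 8 and 2 (TRP, Piezo, ASIC and purinergic channels), 1 and 1 (immediate-early genes) and 8 and 4 (guidance receptors). Gap43 (adjusted p = 0.0816), Atf3 (adjusted p = 0.153) and Gal (adjusted p = 0.0543) no longer passed. The regeneration list's median relative to all genes was -0.71 with either scaling. A change of factors moves all genes nearly alike, so that agreement follows from the measure and is no test of the list. The calls came to 1159 with thinned cells, 1500 with clusters from highly variable genes, 1587 at a Leiden resolution of 2, 1705 with at least 8 cells per sum and 4876 with the bias-adjusted deviance.

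**Figure D1:**
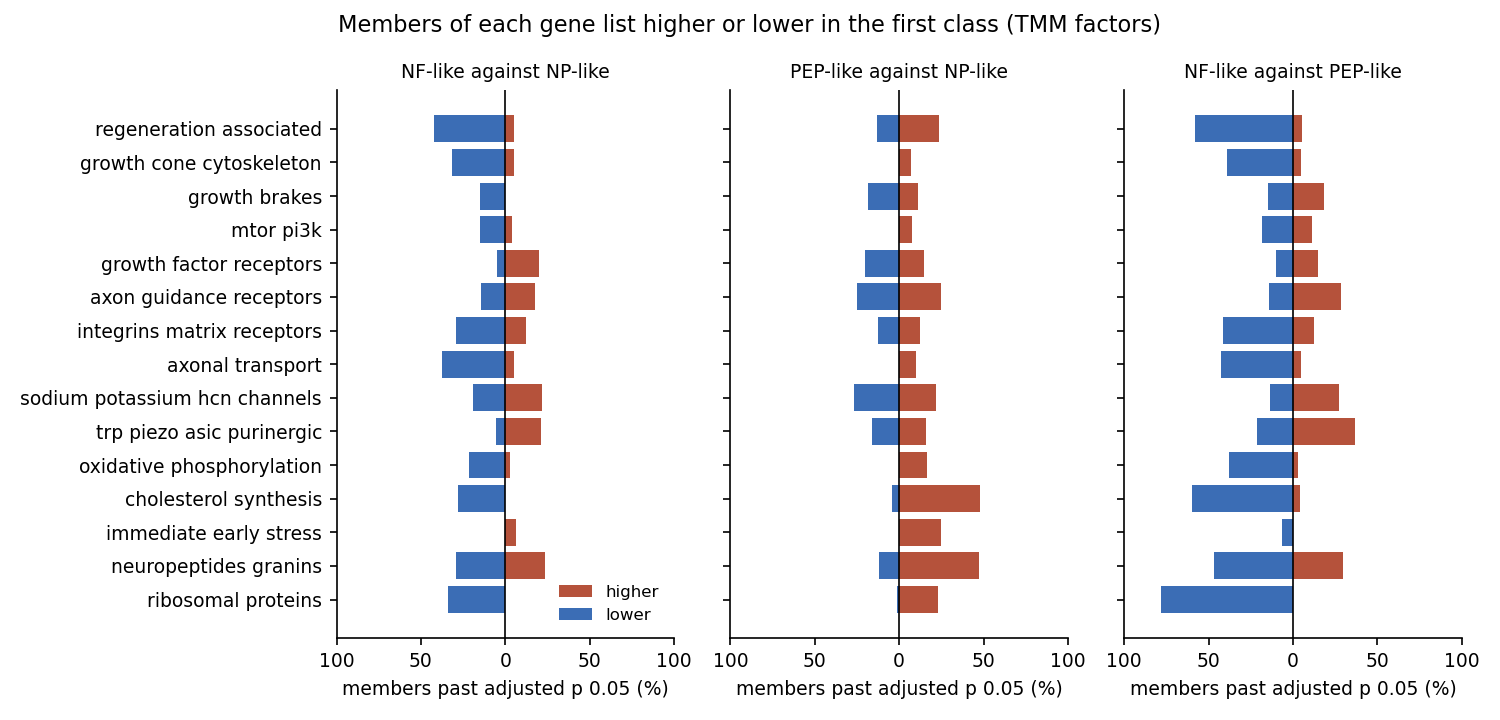
Share of the tested members of each of 15 gene lists (in percent of members) that were higher (red, to the right) or lower (blue, to the left) in the first-named class at an adjusted p under 0.05 in 3 pairwise comparisons, with TMM scaling factors. Regeneration-associated genes had 16 of 38 members lower in NF-like against NP-like and 22 of 38 in NF-like against PEP-like neurons, where RLE factors gave 8 and 16.

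**Figure D2:**
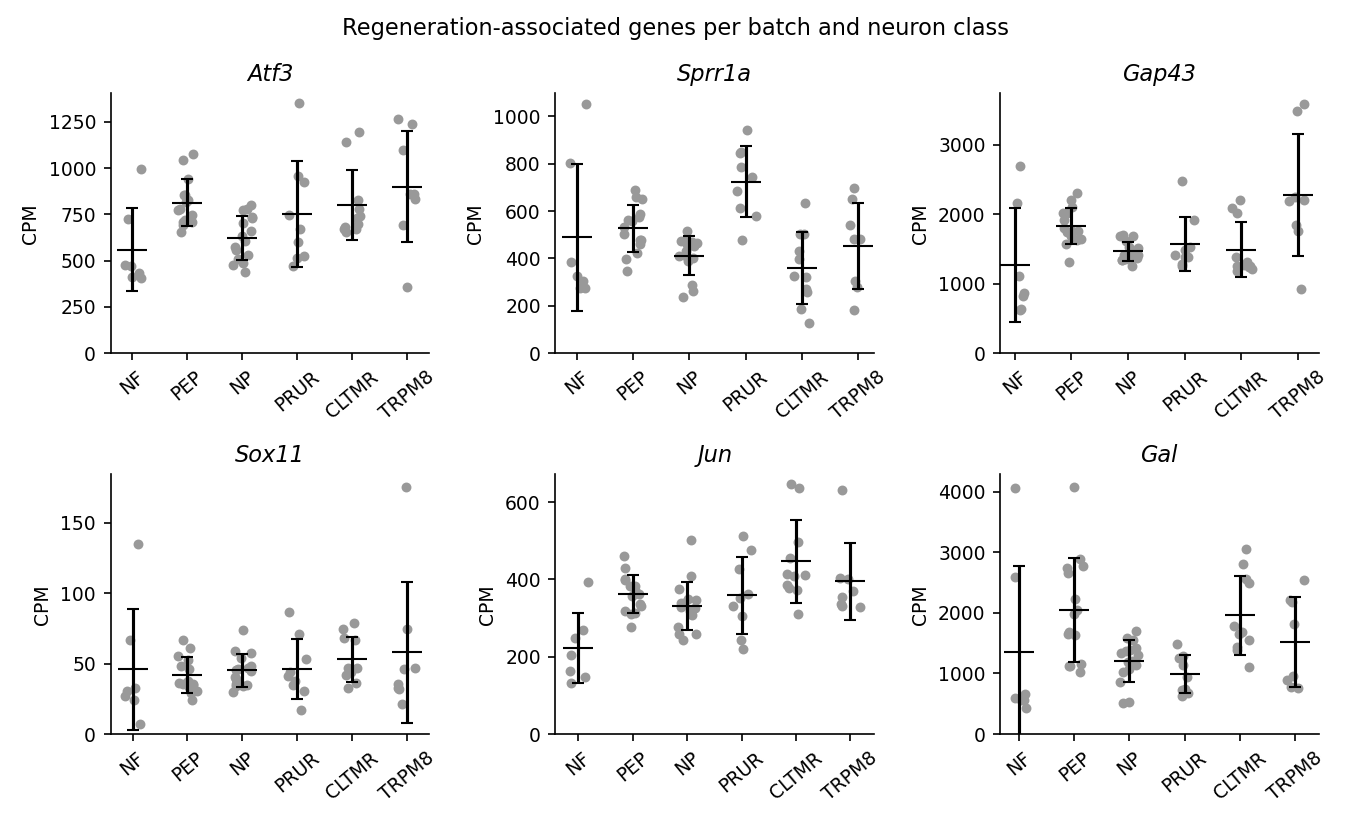
Levels of Atf3, Sprr1a, Gap43, Sox11, Jun and Gal (CPM, linear axis) in the sums of the 6 neuron classes, with grey points for batches and black marks for the mean with SD. Jun had a mean of 222 ± 91.1 CPM in 7 NF-like sums and 362 ± 49.3 CPM in 15 PEP-like sums, and Gap43 of 1271 ± 818 and 1831 ± 264 CPM, a Gap43 difference that did not pass with RLE factors.

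PRUR-like neurons, set against the mean of the other 5 classes, were marked by Calb2, the calcium-binding protein calretinin. Calb2 was at 57.0 ± 35.3 CPM (n = 9 sums). It was higher by 5.53 ± 0.57 on the log2 scale (adjusted p = 4.85e-11) and the membrane protein Emp1 by 4.86 ± 0.33 (adjusted p = 1.18e-17), each in 9 of 9 batches. The same held for the claudin Cldn3 at 4.25 ± 0.37 (adjusted p = 1.36e-13) and the annexin Anxa8 at 4.03 ± 0.25 (adjusted p = 9.42e-20). Cst12 (4.77 ± 0.43, adjusted p = 4.41e-13) and Ifitm1 (4.21 ± 0.25, adjusted p = 4.3e-20), which has close copies, were also higher. Lower were Atp1b1 (-3.42 ± 0.33, adjusted p = 2.42e-12) and the adhesion molecule Cntn1 (-3.42 ± 0.40, adjusted p = 1.34e-09). Lower too were Exoc1l (-3.19 ± 0.65, adjusted p = 0.000169), the growth factor Ptn (-3.04 ± 0.44, adjusted p = 2.1e-07), the calcium pump Atp2b2 (-3.02 ± 0.46, adjusted p = 8.33e-07) and Tafa2 (5.58 ± 3.69 CPM, adjusted p = 3.39e-08, lower in 9 of 9 batches). In all, 1269 genes were higher and 971 lower. Batch counts for PRUR-like, CLTMR-like and TRPM8-like neurons set the class against the other classes that the batch held, which were not always all 5.

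Axon guidance receptors were lower in PRUR-like neurons in 14 of 28 cases and higher in 1 (adjusted over the list alone, 14 and 1). The set test's adjusted p of 4.41e-05 also passed with an estimated correlation (adjusted p = 0.0351). The neural adhesion molecule Nrcam was at -0.79 ± 0.16 (adjusted p = 0.000207) and Plxnd1, a semaphorin receptor, at 0.78 ± 0.26 (adjusted p = 0.0227). The regeneration list had 15 of 38 higher and 1 lower (adjusted over the list alone, 16 and 1; set test adjusted p = 0.00071, adjusted p = 0.4655 with an estimated correlation). The peptide Vip was at 1.94 ± 0.19 (adjusted p = 8.97e-12, 1404 ± 434 CPM) and Sprr1a at 0.78 ± 0.15 (adjusted p = 0.000112, 725 ± 150 CPM, 9 of 9 batches). Cholesterol synthesis had 10 of 25 higher and 0 lower (adjusted over the list alone, 11 and 0; set test adjusted p = 0.00071, adjusted p = 0.359 with an estimated correlation). Msmo1 was at 0.79 ± 0.11 (adjusted p = 1.61e-07). Growth cone genes had 5 of 41 higher and 9 lower (adjusted over the list alone, 5 and 10; set test adjusted p = 0.0209, adjusted p = 0.714 with an estimated correlation). Lower members included Stmn1 (-1.01 ± 0.14, adjusted p = 8.34e-08) and Mapt, the protein tau (-0.93 ± 0.11, adjusted p = 4.07e-09). Growth brakes had 1 of 27 higher and 7 lower (adjusted over the list alone, 1 and 7; set test adjusted p = 0.0209, adjusted p = 0.148 with an estimated correlation). They included the receptor phosphatase Ptprf (-1.45 ± 0.16, adjusted p = 1.1e-10). Oxidative phosphorylation had 0 of 37 higher and 4 lower (adjusted over the list alone, 0 and 1; set test adjusted p = 0.0095, adjusted p = 0.714 with an estimated correlation). No other list passed. The irritant-gated channel Trpa1 (2.67 ± 0.47, adjusted p = 1.6e-05) was higher and Asic1 lower (-2.33 ± 0.27, adjusted p = 6.93e-10). Atf3 (0.03 ± 0.12, adjusted p = 0.898), Gap43 (-0.03 ± 0.13, adjusted p = 0.919), Sox11 (0.06 ± 0.20, adjusted p = 0.896), Jun (0.10 ± 0.11, adjusted p = 0.615) and Gal (-0.48 ± 0.22, adjusted p = 0.137) did not pass. With RLE factors the counts were 12 and 1 (regeneration), 4 and 10 (growth cone) and 0 and 5 (oxidative phosphorylation). The count of calls was 986 with thinned cells, 1056 with clusters from highly variable genes and 450 with at least 8 cells per sum.

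CLTMR-like neurons were marked by Lad1, Nmu and Atp2b2. Lad1, a protein of basement membrane attachments, was at 59.5 ± 31.7 CPM (n = 11 sums) and higher than the mean of the other 5 classes by 5.26 ± 0.35 (adjusted p = 6.39e-18). The peptide neuromedin U (Nmu) was higher by 4.13 ± 0.40 (adjusted p = 1.28e-11) and Atp2b2 by 3.30 ± 0.26 (adjusted p = 4.69e-15), each in 11 of 11 batches. Exoc1l (3.52 ± 0.36, adjusted p = 5.12e-11), the matrix metalloproteinase Mmp9 (3.44 ± 0.42, adjusted p = 8.51e-09) and Nell2 (3.06 ± 0.35, adjusted p = 1.48e-09) were also higher. Lower were the Wnt modulator Dkk3 (-3.04 ± 0.26, adjusted p = 1.18e-13) and Samd9 (-2.94 ± 0.29, adjusted p = 3.07e-11). Lower too were complement factor I (Cfi, -2.58 ± 0.40, adjusted p = 1.63e-06), the prostacyclin receptor Ptgir (-2.48 ± 0.28, adjusted p = 8.66e-10), Tnfaip6 (-2.40 ± 0.52, adjusted p = 0.000499) and the granin Scg2 (-2.39 ± 0.26, adjusted p = 5.09e-10). In all, 1032 genes were higher and 1084 lower.

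Axon guidance receptors were higher in CLTMR-like neurons in 14 of 28 cases and lower in 3 (adjusted over the list alone, 14 and 4; set test adjusted p = 0.000308, adjusted p = 0.0795 with an estimated correlation). Cntn1 was at 1.90 ± 0.26 (adjusted p = 7.79e-08) and the ephrin Efnb1 at 2.63 ± 0.37 (adjusted p = 2.5e-07). Growth cone genes had 9 of 41 higher and 0 lower (adjusted over the list alone, 9 and 0; set test adjusted p = 0.00745, adjusted p = 0.578 with an estimated correlation). Cholesterol synthesis had 7 of 25 higher and 1 lower (adjusted over the list alone, 7 and 1; set test adjusted p = 0.00745, adjusted p = 0.551 with an estimated correlation). Integrins and matrix receptors had 4 of 24 higher and 4 lower (adjusted over the list alone, 4 and 5; set test adjusted p = 0.0209, adjusted p = 0.55 with an estimated correlation). Itga7 was at 2.38 ± 0.18 (adjusted p = 1.99e-15, 325 ± 111 CPM). Ribosomal protein genes had 0 of 65 higher and 7 lower (adjusted over the list alone, 0 and 3; set test adjusted p = 0.00102, adjusted p = 0.578 with an estimated correlation). No other list passed the set test here. The chloride channel Ano1 (3.78 ± 0.58, adjusted p = 1.35e-06) and the opioid precursor Pdyn (3.67 ± 0.46, adjusted p = 1.08e-08) were higher, and Trpa1 (-4.70 ± 0.77, adjusted p = 4.67e-06) and Fos (-3.34 ± 0.95, adjusted p = 0.00867) lower. Jun was higher by 0.46 ± 0.10 (adjusted p = 0.000901, 10 of 11 batches) and Gal by 0.60 ± 0.20 (adjusted p = 0.0296, 10 of 11). Sprr1a was lower (-0.46 ± 0.16, adjusted p = 0.0356, 8 of 11), while Atf3 (0.21 ± 0.11, adjusted p = 0.213), Gap43 (-0.07 ± 0.13, adjusted p = 0.765) and Sox11 (0.31 ± 0.19, adjusted p = 0.271) did not pass. The count of calls was 1016 with thinned cells, 1239 with at least 5 and 1287 with at least 8 cells per sum, and 3572 with limma voom. With at least 8 cells per sum Sprr1a was at 0.24.

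TRPM8-like neurons were marked by Cox6a2, a subunit of cytochrome c oxidase known from heart and muscle, and by the potassium channel Kcnk2. Cox6a2 was at 132 ± 144 CPM (n = 8 sums). It was higher than the mean of the other 5 classes by 4.60 ± 0.51 (adjusted p = 7.32e-10) and Kcnk2 by 4.05 ± 0.33 (adjusted p = 1.8e-14), each in 8 of 8 batches. The same held for the protocadherin Pcdh9 at 3.62 ± 0.31 (adjusted p = 9.61e-14) and the matrix proteoglycan Vcan at 3.35 ± 0.54 (adjusted p = 4.73e-06). Ptchd1 (3.75 ± 0.37, adjusted p = 1.87e-11) and the BMP antagonist Chrdl2 (3.43 ± 0.32, adjusted p = 4.6e-12) were also higher. Lower were the nociceptor sodium channel Scn10a (-3.54 ± 0.54, adjusted p = 1.42e-06) and Ppfibp2 (-3.19 ± 0.45, adjusted p = 2.85e-07). Lower too were Tmem45b (-2.88 ± 0.41, adjusted p = 4.35e-07), the potassium channel Kcna1 (-2.86 ± 0.38, adjusted p = 9.58e-08), Popdc3 (-2.85 ± 0.39, adjusted p = 1.42e-07) and Epcam (-2.79 ± 0.64, adjusted p = 0.00111, 7 of 8 batches). In all, 902 genes were higher and 1515 lower.

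Genes of the mitochondrial respiratory chain and of the ribosome were higher in TRPM8-like neurons, in 24 of 37 and 47 of 65 cases with 0 lower in either list (adjusted over the list alone, 31 and 48 higher). Their set tests gave adjusted p = 2e-18 and adjusted p = 1.93e-28, and both were at adjusted p = 0.0869 with an estimated correlation. Atp5po was at 0.52 ± 0.08 (adjusted p = 1.17e-06). The median mitochondrial share of UMIs per cell was 2.71% in TRPM8-like, 2.21% in NF-like, 1.79% in PRUR-like, 1.76% in PEP-like, 1.53% in CLTMR-like and 1.48% in NP-like cells. Growth cone genes had 17 of 41 higher and 2 lower (adjusted over the list alone, 19 and 3; set test adjusted p = 3.91e-08, adjusted p = 0.22 with an estimated correlation). Stmn1 was at 0.94 ± 0.13 (adjusted p = 3.47e-07) and Mapt at 0.83 ± 0.11 (adjusted p = 9.17e-08). Transport genes had 9 of 40 higher and 1 lower (adjusted over the list alone, 10 and 1; set test adjusted p = 0.0138, adjusted p = 0.353 with an estimated correlation). Guidance receptors had 6 of 28 higher and 4 lower (adjusted over the list alone, 6 and 4; set test adjusted p = 0.0213, adjusted p = 0.251 with an estimated correlation). They included the netrin receptor Dcc (5.12 ± 0.57, adjusted p = 2.54e-09) and Nrp2 (-2.39 ± 0.62, adjusted p = 0.00425). The regeneration list had 10 of 38 higher and 5 lower (adjusted over the list alone, 11 and 7; set test adjusted p = 0.0324, adjusted p = 0.542 with an estimated correlation). That list's median was 0.11 and its mean -0.06. Cholesterol synthesis had 5 of 25 higher and 1 lower (adjusted over the list alone, 5 and 1; set test adjusted p = 0.0316, adjusted p = 0.503 with an estimated correlation). None of the remaining 8 lists passed. Gap43 was higher by 0.58 ± 0.14 (adjusted p = 0.00151, 2278 ± 883 CPM, 7 of 8 batches) and Atf3 by 0.38 ± 0.13 (adjusted p = 0.0295, 900 ± 302 CPM, 7 of 8). Of the others, Jun (0.27 ± 0.12, adjusted p = 0.11, and adjusted p = 0.0410 with RLE factors), Sprr1a (-0.08 ± 0.18, adjusted p = 0.816), Sox11 (0.20 ± 0.23, adjusted p = 0.583) and Gal (0.21 ± 0.23, adjusted p = 0.558) did not pass. The median depth was 132162 UMIs in TRPM8-like and 224392 UMIs in NP-like cells. The TRPM8-like sums with the fewest UMIs (batches 28-1, 31 and 27, 155695 to 283195 UMIs) had the highest Gap43 (3583, 3486 and 2246 CPM). They also had the highest Atf3 (1268, 1240 and 1097 CPM). Batch 26, with 1032044 UMIs, had the lowest (929.5 and 355.2 CPM). Whether depth bears on these 2 genes was not tested. RLE factors gave 1208 higher and 1202 lower calls, with 31 and 0 (respiratory chain), 50 and 0 (ribosome), 20 and 0 (growth cone), 13 and 5 (regeneration), 11 and 1 (transport) and 5 and 0 (cholesterol). The calls came to 607 with thinned cells, 992 with at least 5 cells per sum, 1579 with NP-like cluster 6 alone and 1598 with the bias-adjusted deviance.

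NF-like cells yielded fewer UMIs than NP-like cells by a mean of -1.004 ± 1.79 on the log2 scale (SD over 7 batches, lower in 5), a difference within the spread between batches (exact two-sided sign-flip test, p = 0.188). They had fewer detected genes than NP-like cells by -0.45 ± 0.51 (lower in 5 of 7 batches, exact test, p = 0.0781), fewer UMIs than PEP-like cells by -1.02 ± 1.94 (exact test, p = 0.188) and fewer genes by -0.40 ± 0.57 (exact test, p = 0.125). PEP-like and NP-like cells differed by -0.06 ± 0.62 in UMIs (n = 15 batches, permutation test, p = 0.691) and by -0.05 ± 0.14 in genes (permutation test, p = 0.182). After adjustment over these 6 comparisons the smallest p was 0.225. Among cells with at least 3000 genes the NF-like differences turned to 0.81 in UMIs and 0.19 in genes against NP-like cells and to 0.79 and 0.28 against PEP-like cells, over 5 batches.

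The mean log2 CPM of 40 regeneration-associated genes in NP-like cells alone had a median of 7.51 over the 16 batches, from 7.26 in batch 23 to 7.66 in batch 30. Over all named neurons, whose class shares differ between batches, the median was 7.63, from 7.28 in batch 24 to 7.74 in batch 30. Over all named neurons Atf3 ran from 592 CPM (batch 30) to 901 CPM (batch 28-1) with a median of 670 CPM. Sprr1a ran from 205 CPM (batch 24) to 561 CPM (batch 28-3) and Gal from 496 CPM (batch 24) to 2084 CPM (batch 22). Gap43 ran from 1339 CPM (batch 24) to 1863 CPM (batch 28-1) and Jun from 260 CPM (batch 20) to 417 CPM (batch 23). The immediate-early gene Fos had a median of 6.32 CPM, with 1.49 CPM in batch 32 as the lowest and 138 CPM in batch 24, 92.5 CPM in batch 23 and 61.3 CPM in batch 28-1 as the highest.

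The PRUR-like peptides Sst and Nppb were also counted outside their class. A Sst UMI was present in 60 of 60 PRUR-like cells at 1135 CPM, in 77.8% of 302 NP-like cells (exact 95% interval 72.7 to 82.4%) at 20.1 CPM and in 73.0% of 211 PEP-like cells (66.5 to 78.9%) at 19.2 CPM. These intervals count cells as independent and measure no spread between batches, with which the level changed. The median depths of PRUR-like, NP-like and PEP-like cells were 231927, 224392 and 206536 UMIs. In TRPM8-like, CLTMR-like and NF-like cells Sst was at 67.3, 35.1 and 34.2 CPM. Over 16 batches, the Sst and Nppb level of NP-like and PEP-like cells rose with the PRUR-like cells' share of the batch's UMIs that are Sst and Nppb (Pearson r = 0.776, permutation p = 0.0004, Spearman rho = 0.865, permutation p = 3e-05). These were the 2 coefficients computed, with adjusted p = 0.0004 and adjusted p = 6e-05. Without the 2 batches farthest from the median share, r was 0.670 and rho 0.807.

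**Figure D3:**
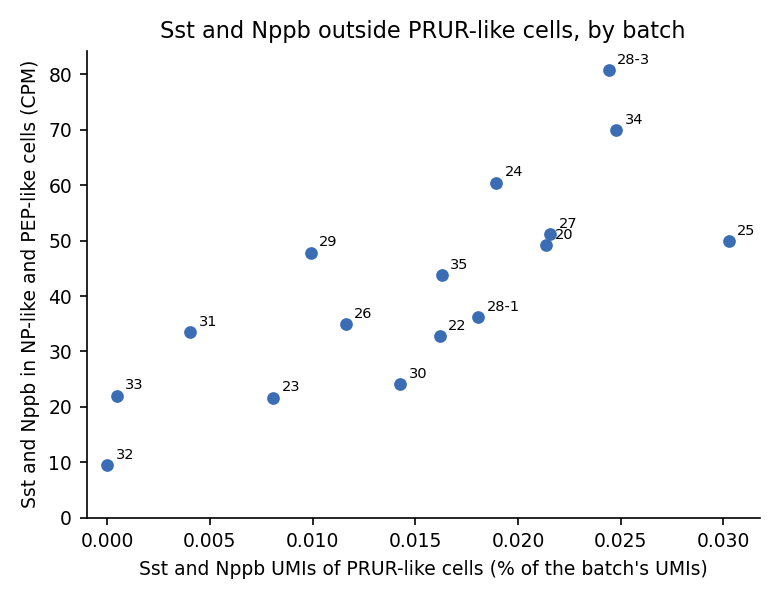
Level of Sst and Nppb together in the NP-like and PEP-like cells of each of 16 batches (CPM, vertical axis) against the share of all the batch's UMIs that were Sst and Nppb UMIs of PRUR-like cells (percent, horizontal axis), where a point is a batch. The level rises with the share, with a Spearman rho of 0.865 and a median level of 40.0 CPM.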

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

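Of the tests in this part, the class labels shuffled within batches, the share of the cluster with Fos in its largest batches, and the outlier tests of PRUR-like and TRPM8-like sums were chosen after the results were seen.

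Single sums stood far from the others of their class in 12 of 76 groups tested, where chance gives about 1 in 20 for independent groups of normally spread values. The values were CPM without a log, the groups shared sums, and all 12 were the highest of their group. So the number flagged cannot be set against that rate. A first set of 40 groups held 6 of them, and the 36 groups added after that set's result was seen held the other 6. In NF-like sums, batch 28-3 (3 cells, 184310 UMIs) was highest for Synpr at 42.29 CPM (next batch 14.6), Abi3bp at 241.7 CPM (29.2), Gzmbl3 at 241.7 CPM (49.0) and Apoh at 36.25 CPM (17.0). These are genes that were lower in NF-like than in NP-like or PEP-like neurons. Ramp3, a gene higher in PEP-like neurons, was at 102.5 CPM in the NF-like sum of batch 35 (next 26.9) and Crh at 83.06 CPM in that of batch 20 (next 8.96). In PRUR-like sums, Emp1 was at 950.6 CPM in batch 28-1 (next 364) and Atp2b2 at 17.46 CPM in batch 30 (next 4.60). In TRPM8-like sums, Kcna1 was at 42.74 CPM in batch 34 (next 19.5), Epcam at 29.72 CPM in batch 31 (next 9.16), and Sox11 and Jun at 175.6 and 630.7 CPM in batch 28-1 (next 74.9 and 404; 4 cells, 155695 UMIs).

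Haemoglobin genes were markers used to form and name a cluster of 47 cells left out of the classes, so their level there follows from how it was made. Hba-a1 was at 183.2 CPM, Hba-a2 at 108 CPM and Hbb at 32.71 CPM, against 2.51, 1.04 and 0.303 CPM in the named neurons.

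Shuffling the class labels within batches does not decide whether chance can be excluded for the counts of called genes. The classes came from clusters of the same cells, and the shuffle did not repeat the clustering. The real labels alone, 1 of 31 splits, gave as many calls in each of the 6 comparisons: 2307 for NF-like against NP-like (highest other 52), 2221 for PEP-like against NP-like (27), 3041 for NF-like against PEP-like (103), 2240 for PRUR-like (33), 2116 for CLTMR-like (11) and 2417 for TRPM8-like neurons (3).

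Sst and Nppb in NP-like and PEP-like cells followed the PRUR-like cells' contribution to their batch (Spearman rho 0.865), as RNA or barcodes shared among cells pooled in a batch would give. The other classes were not part of that test. A low level of the cells' own Sst and Nppb could not be told apart from none, because the level extrapolated to a batch without PRUR-like UMIs was 13.5 CPM with a 95% interval of -10.8 to 26.4 CPM. Batch 32, with 0 PRUR-like cells, had 9.57 CPM. The labels give no group that would offer a biological explanation, and none was tested. The same sharing may add a low background to other abundant class genes, which was not tested beyond the rho of 0.865.

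Fos and Fosb, immediate-early genes induced by neuronal activity, were among the 10 leading genes of 1 of the 3 NP-like clusters, at 104 and 36.6 CPM against 2.81 and 0.480 CPM and 8.37 and 4.98 CPM in the others. Its first gene was 7SK-278, and the non-coding RNAs U6-341, 5S-rRNA-130 and 7SK-6 were also among the 10, which was not examined further. A few batches and shallow or damaged cells both stay open as explanations. Batches 23 and 24 held 35.6% of its cells, which came from 15 batches, but Fos was highest over all named neurons in batches 24, 23 and 28-1 (138, 92.5 and 61.3 CPM, median 6.32 CPM). Fos was among the leading genes of a cluster of 28 cells in 6 batches with no cell filter or a resolution of 0.5, of 32 in 7 with a resolution of 2, of 33 in 5 with highly variable genes and of 57 in 14 among cells with at least 3000 genes. With the panel centred per batch neither gene was among the 10 leading genes of a cluster, including the NP-like one led by Th (69 cells in 15 batches). The UMIs of its cells differed from those of other NP-like cells by 0.324 on the log2 scale (-0.148 to 0.796, 10 batches, permutation p = 0.158) and the mitochondrial share by 0.599 points (-0.198 to 1.40, permutation p = 0.211). No biological explanation was tested.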

How the results depend on the processing

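The alternatives chosen after the data were seen were the bias-adjusted deviance, limma voom, each NP-like cluster alone, NP-like cluster 6 left out, batches 23 and 24 left out, the cells highest in 5 core glial markers left out, and all those for PRUR-like, CLTMR-like and TRPM8-like neurons. Over all alternatives, 194 counts of called genes stayed within 1.5 times and 25 moved. Named genes kept direction and side of the threshold in 13351 cases, lost the call in 868, gained it in 59 and changed sign in 36. The named genes were picked from the main fit, and 6116 of the unchanged cases came from leaving out 1 batch, where most sums are shared. With clusters from highly variable genes 205 stayed the same, 53 lost the call and 13 changed sign. With at least 8 cells per sum these numbers were 218, 105 and 5. Results of single gene lists stayed the same in 161 cases, were weaker in 19 and stronger in 15. The cause was not tested except where given.

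Thinning each cell to 30000 UMIs, which tests 6797 genes and leaves out 196 cells, gave 729 calls for NF-like against NP-like, 1320 for PEP-like against NP-like, 1159 for NF-like against PEP-like, 986 for PRUR-like, 1016 for CLTMR-like and 607 for TRPM8-like, of which 591, 1101, 912, 868, 842 and 540 were called the same way without thinning. At least 8 cells per sum, which leaves fewer sums, gave 1705 for NF-like against PEP-like, 450 for PRUR-like and 1287 for CLTMR-like, and at least 5 gave 1239 for CLTMR-like and 992 for TRPM8-like. Clusters from highly variable genes gave 1500 for NF-like against PEP-like and 1056 for PRUR-like, and a resolution of 2 gave 1587 for NF-like against PEP-like. NP-like cluster 6 alone gave 1217 for NF-like against NP-like, 1111 for PEP-like against NP-like and 1579 for TRPM8-like. The bias-adjusted deviance gave 4179 for NF-like against NP-like, 4097 for PEP-like against NP-like, 4876 for NF-like against PEP-like and 1598 for TRPM8-like, and limma voom 3485, 4565 and, for CLTMR-like, 3572. With 1 batch left out, counts ran from 1504 (without batch 26) to 2528 for NF-like against NP-like, 1916 to 2221 for PEP-like against NP-like, 2268 to 3207 for NF-like against PEP-like, 1880 to 2385 for PRUR-like, 1800 to 2283 for CLTMR-like and 1861 to 2517 for TRPM8-like.

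With an estimated correlation, 0, 0 and 0 lists passed in the 3 pairwise comparisons, where 4, 5 and 7 had passed at the preset one. Without the cells highest in 5 core glial markers, 7 passed for NF-like against NP-like. With clusters from highly variable genes the NP-like share was 10.06%, with 557 cells in no class. Among cells with at least 3000 genes, the NF-like differences changed sign to 0.81 (UMIs) and 0.194 (genes) against NP-like and 0.792 and 0.277 against PEP-like cells (exact p = 0.0625, 0.0625, 0.188 and 0.0625, 5 batches), since shallow cells are left out by construction. The PEP-like against NP-like difference in genes was -0.0739 (permutation p = 0.0435) there, and in UMIs 0.084 with no cell filter.

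With clusters from highly variable genes the NF-like class held largely other cells, and the NP-like and PEP-like classes were smaller. The NF-like class there had 81 cells, of which 25 were among the 49 of the main clustering. The NP-like class had 90 cells, of which 88 were among the 302 of the main clustering. For the PEP-like class 132 of 139 cells were among the 211 of the main clustering. For the PRUR-like class 51 of 57 were among its 60, and for the TRPM8-like class 30 of 43 were among its 41. Clusters from highly variable genes reversed Dynll2 NF-like against NP-like (-0.048) and, in the same comparison, Ddit4 (-0.68), Rbl2 (0.14), Ncam1 (1.66), Sdc3 (0.028), Trpm3 (0.29), Atp5f1a (0.20), Pcsk1 (0.88) and Vip (0.43). They also reversed Ier3 (-0.091) for PEP-like against NP-like, Klc4 (-0.10) for NF-like against PEP-like, and Ppp3ca (0.011) and Itga6 (0.069) for TRPM8-like. A resolution of 2 reversed Sdc2 (-0.37), Ier3 (-0.057), Vip (0.063) and Jun (0.15) for NF-like against NP-like, and, for NF-like against PEP-like, Fgfr1 (-0.65), Nrp2 (-0.15), Jun (0.024) and Nmb NF-like against PEP-like (-2.13), where Nmb was also at -1.63 with a resolution of 0.5 and -0.44 with no cell filter. At least 8 cells per sum reversed Cd9 NF-like against NP-like (-1.55), Itga7 (-0.17) and Fermt2 (-0.21) for NF-like against PEP-like, and Rpl26 (0.094) and Sprr1a (0.24) for CLTMR-like. NP-like cluster 3 alone reversed Ncam1 (0.29) and Vip (0.046) for NF-like and Ier3 (-0.090) for PEP-like against NP-like. NP-like cluster 6 alone reversed Dync1i1 NF-like against NP-like (-0.078), and Ngfr (-0.056), Dync1i1 (-0.072), Cox7b (-0.21) and Stard4 (0.23) for PEP-like against NP-like.

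Without batches 23 and 24, 394 named genes kept their call and 1 lost it, and with RLE factors 378 kept it. Leaving out the cells highest in all glial markers left too few NF-like cells, at least 3000 genes or highly variable genes gave no CLTMR-like class, and at least 8 cells left too few TRPM8-like sums, so these gave no value.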

Other observations

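Of the tests in this part, the one on scaling factors and the choice of 5 core glial markers came after the results were seen.

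The NP-like class held 3 clusters with near-equal P2rx3 (439, 450 and 423 CPM). The largest was led by Ntsr1, a neurotensin receptor, at 65.1 CPM and by Chrna3 at 81.0 CPM. Another was led by Gzmbl3 (389 CPM), Dapk2 (114 CPM) and the lysophosphatidic acid receptor Lpar3 (81.2 CPM), and the one with Fos also had Th at 123 CPM, against 5.84 and 3.98 CPM in the others, Calcb at 351 CPM and Grik1 at 149 CPM. Sprr1a, a regeneration-associated gene, was at 510, 396 and 274 CPM in these 3 clusters in that order, and Atf3 at 648, 560 and 581 CPM. The clusters were not tested against each other.

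More genes were lower than higher in NF-like against NP-like neurons (63.7% of calls). The tests leave its source open. Without the cells highest in 5 core glial markers 59.0% of calls were lower, but the share ran from 49.6% (without batch 27) to 65.5% with single batches left out, so glial RNA picked with NF-like cells stays open. RLE factors left 36.3% of calls lower, which follows from raising the median over all genes by 0.17. Leaving out batch 24, whose only sum was NP-like and cannot carry this contrast, gave 54.4%. Leaving out batch 23, also without an NF-like sum, gave 62.9%, and leaving out both gave 62.7%. The share thus depends on what all sums share in the fit, which includes the scaling factors and the tested genes. Which factors are right was not tested, so how far the scaling factors between libraries are the source stays undecided. The share was also 78.8% with at least 8 cells per sum and 51.2% with batches 28-1 and 28-3 as 1 batch. Fewer UMIs per cell cannot be told apart, since thinning gave 51.4% but called only 729 genes. The labels give no group that would offer a biological explanation, and none was tested.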
